A study of Homo sapiens with 2 samples.

How the data were processed

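RNA was measured in MDA-MB-231 cells, an established human breast cancer line with a basal-like, invasive phenotype that is widely used in bone metastasis models. Per the labels' protocols, cells were transduced with retroviruses, selected with the antibiotic G-418 for 10 days starting 48 hours later, and pooled. There were 2 samples, 1 carrying the vector control and 1 carrying SR-IκBα, the name in common use for the super-repressor form of the NF-κB inhibitor IκBα. Total RNA was extracted with Trizol, cleaned on a column, labelled with biotin during in vitro transcription and hybridised to 1 Affymetrix array per sample, per the labels' protocols. The titles also carry the codes P1 and P2, whose meaning the labels do not give.

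The deposited values are signal intensities on a linear scale, 1 per probe set, which the authors computed with the one-step Tukey biweight of MAS5, per the labels and per the submitters' processing notes. The MAS5 version, detection calls and chip scans are not given in the sources used here. The table held 22283 probe sets, of which 68 were control probe sets. The 2% trimmed mean of the deposited values was 500.2 on both arrays, so the values had been scaled to a common level. Such scaling removes any difference in total signal between the arrays. Summaries of this kind subtract mismatch-probe signal, which makes low values variable.

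The arrays were scaled again to equal 2% trimmed means, which left them almost as deposited. Signals were floored at 170.4, the mean of the medians of the non-control probe sets, and taken to log2. A gene was measured when its brighter array lay above the floor. Where the dimmer array lay at or below the floor, the fold is a lower bound and is written "at least". Names came from a platform annotation that lists 20114 of the probe sets. Of these, 19071 had 1 gene symbol and 1043 had several, and no gene was named from the latter. The other 2169 probe sets, 2107 of them not controls, were left unnamed. Entrez identifiers of 19059 of the probe sets with 1 symbol matched the RefSeq table of assembly GRCh38.p14, and 0 symbols needed updating. No coordinates are given, because the build behind the files is not stated. A gene was represented by its probe set with the highest mean signal. This gave 11963 genes, 7750 of them measured.

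There was 1 array per group, so no significance test between groups is possible, and no p-value is given. Genes are described by a fixed rule of size, a ratio of at least 2-fold. As technical yardsticks, the log2 ratios of the 18 probe sets for hybridisation controls had an SD of 0.22, and probe sets of the same gene differed with a pooled within-gene SD of 0.43 over 2246 genes. Neither covers the spread between cultures. The number of arrays limits the precision of every value.

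Before the data were examined, 30 gene lists holding 638 genes were fixed. Of these, 5 were primary, 4 on NF-κB and 1 on bone metastasis. The other 21 pathway lists and 4 lists of markers of other cell types gave context. The lists were written from general knowledge and share members. Of the 638 genes, 570 had a named probe set and 68 did not. A list's median log2 ratio over its measured members was set among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins of the measured genes. A percentile under 2.5 or over 97.5 is described as standing apart. The percentile describes these 2 arrays and is not a test between conditions. Lists with under 5 measured members got no percentile.

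The genes named in the text were chosen by a rule fixed before the data were examined. It took NFKBIA, 1 further gene that is not reported here because no probe set was named for it, the 10 highest and 10 lowest ratios among genes whose probe sets above the floor all had the same sign, the 4 largest ratios in each primary list, and the 3 largest in the direction of each other list that stood apart. The rule named 43 genes. A gene with 1 probe set above the floor met the same-sign condition by itself. Other genes are named as members of the fixed lists or are said to have been chosen after their values were seen.

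Alternatives covered other scalings, with no further scaling, quantile, loess with a span of 30% of the probe sets, or centring on the median of measured genes. They covered floors at the 25th and 75th percentile, no floor with a pseudocount of 1, the median over a gene's probe sets, leaving out probe sets whose names end in _x_at or _s_at, thresholds of 1.5-fold and 3-fold, and random lists without matching. The procedure was tested on simulated data in which 200 of the measured genes were changed. Among genes bright enough for a 2-fold call, 89.7% of those lowered by 1.5 log2 units and 93.9% of those raised by 1.5 were recovered, as were 100% of those changed by 2 units in either direction. Of all 50 genes lowered by 2 units, 62% were recovered, because the floor hides losses of dim genes. Of 7264 unchanged genes, 1.06% passed the 2-fold rule. The simulated noise had the same SD, 0.40 log2 units, at every signal. In the data, with measured genes in 4 equal groups by signal, the log2 ratios had an SD of 0.58 in the second dimmest group and 0.34 in the brightest. The 1.06% is therefore not a noise rate to set against the observed counts. Of 100 unchanged lists of 15 genes, 8 stood apart, and of 100 lists lowered by 0.4 log2 units, 90 did. The lists were lowered after flooring, so the 90 does not allow for losses that the floor hides in dim genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.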

Results

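Expression profiles were collected from 2 pools of MDA-MB-231 breast cancer cells, 1 transduced with a retroviral vector control and 1 with a retrovirus for SR-IκBα, a form of IκBα used to hold NF-κB in the cytoplasm. The series was designed to find target genes of NF-κB and to relate them to osteolytic bone metastasis. Each group had 1 array, so the values below carry no replicate error and the comparison is between these 2 arrays. The median signal was 171.9 on the vector control array and 169.1 on the SR-IκBα array. On floored log2 signals, the arrays correlated across the 7750 measured genes with a Pearson r of 0.96, genes not being independent replicates. Over all non-control probe sets, without a floor, r was 0.89. The median log2 ratio of SR-IκBα to vector control was -0.01, with quartiles of -0.28 and 0.26.

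NFKBIA, which encodes IκBα, had a signal of 4453 with the vector control and 2893 with SR-IκBα, 1.54-fold lower, on its single named probe set. Endogenous NFKBIA is itself a target of NF-κB, and whether the probes lie within the introduced cDNA is not given in the sources used here. The value therefore does not check the labels in either direction.

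The lowest ratios on the SR-IκBα array belonged to inflammatory chemokines and cytokines. CXCL8, the neutrophil chemoattractant interleukin-8, had a signal of 8936 in the vector control and 235.4 with SR-IκBα, 38.0-fold lower. Its other probe set gave 28.7-fold. CXCL1 and CXCL2, neutrophil-attracting chemokines of the same family, were at least 26.2-fold and at least 8.32-fold lower, from signals of 4466 and 1419 to values below the floor. IL6, a cytokine with broad effects on inflammation and bone turnover, was at least 6.53-fold lower, from 1113. IL1B, a proinflammatory cytokine, was 3.62-fold lower on its brightest probe set and 1.78-fold lower on its other. Among genes whose probe sets above the floor all had the same direction, the lowest 10 also held INHBA, the activin beta A subunit, at 3.91-fold lower, PLCG1, a phospholipase C, at 3.63-fold lower on its brightest probe set and 1.43-fold lower on its other, and TTC38, TSSC4 and the transcription factor TFAP4, at least 3.82-fold, 3.39-fold and 3.33-fold lower.

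In total 150 of the 7750 measured genes were at least 2-fold lower with SR-IκBα, 135 were at least 2-fold higher, and 7465 (96.3%) lay within 2-fold. In 67 of the lower and 53 of the higher genes the dimmer array was at the floor. At least 4-fold, 4 genes were lower (CXCL8, CXCL1, CXCL2 and IL6) and 1 was higher. That gene was NDRG2, a member of the NDRG family, at least 4.04-fold higher. These counts depended on the floor, and with the floor at the 25th percentile 105 genes were at least 4-fold lower and 88 higher. The rest of the highest 10 among genes whose probe sets above the floor all had the same direction were COMMD8 (3.56-fold), the kinetochore protein gene ZW10 (3.48-fold), the tRNA exportin gene XPOT (at least 3.26-fold), the iron transporter gene SLC11A2 (at least 3.25-fold), PADI1 (at least 3.23-fold), TAF5L (at least 2.97-fold), MXRA8 (at least 2.94-fold), PRRC1 (at least 2.84-fold) and the proteasome component gene SEM1 (2.84-fold). In SLC11A2 the other probe sets above the floor were 1.06-fold and 1.04-fold higher, so its large ratio rests on 1 probe set. Each other gene of the highest 10 had 1 probe set above the floor, so its ratio could not be checked this way. NDRG2 had 3 named probe sets, and the others were not above the floor on either array. Among the lowest 10, TTC38 had 3 and INHBA 2, likewise with 1 above the floor. Genes left out of these ranks because their probe sets differed in direction included EID1, DIO2 and PEG10, with log2 ratios of 1.86, 1.79 and 1.53, and CUX1, with -1.97. These left-out genes were chosen after their values were seen.

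**Figure D1:**
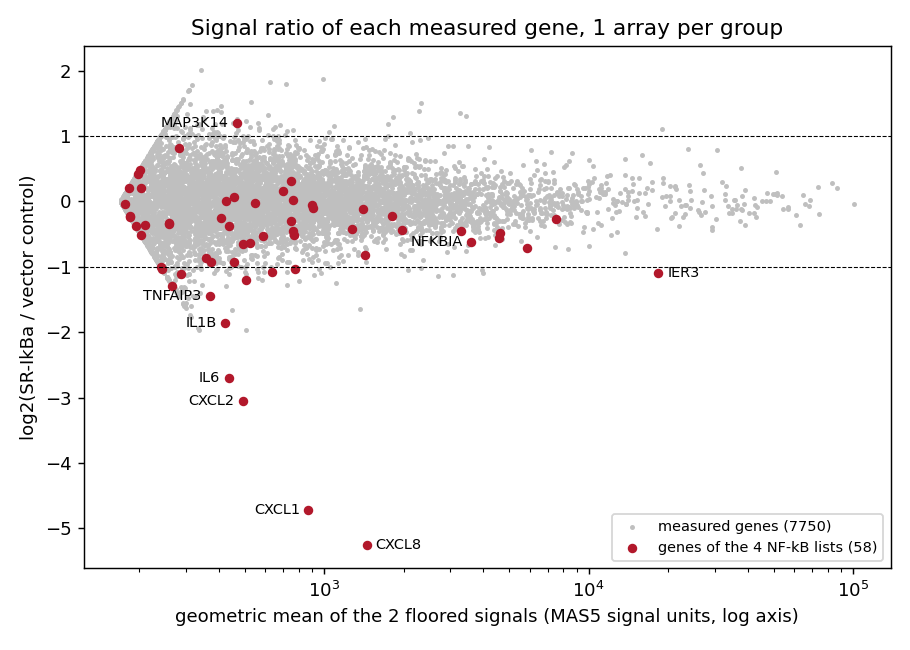
Each point is a measured gene, with the geometric mean of its floored MAS5 signals on a log axis and the log2 ratio of the SR-IκBα array to the vector control array; red points are the 58 measured genes of the 4 NF-κB lists, and dashed lines mark 2-fold. CXCL8 and CXCL1 lie at -5.25 and -4.71, apart from all other genes, and the straight left-hand edges come from the floor of 170.4.

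Cytokines and chemokines with known NF-κB sites were lower as a group. Of 16 measured members, 14 were lower and 2 higher, 7 were at least 2-fold lower and 0 at least 2-fold higher. In most of these members the dimmer array was at or below the floor, so their ratios are only bounds. Their direction follows from which array lay above the floor. Among them CSF3, IL1A and IL24 had vector control signals of 220.6, 201 and 198.1, near the floor. The list median was -0.82 on the log2 scale, below all 10000 random lists of matched signal (percentile 0), whose middle 95% ran from -0.26 to 0.25. Besides the genes above, CCL2, a monocyte chemoattractant, was at least 2.45-fold lower, and CSF1, the macrophage growth factor required for osteoclast formation, was 2.31-fold lower. CSF1 had 4 named probe sets, 1 of them above the floor. CXCL3 was lower, from a signal of 340.6 to 55.9, which is below the floor. Its fold is therefore only a lower bound, and that bound lay just short of 2-fold, so CXCL3 is not among the 7. CCL5 and IL23A were the members that were higher, at least 1.34-fold and 1.39-fold, both from values below the floor, and the probe sets of IL23A differed in direction. With the CXC chemokine genes left out, an alternative added after the data were seen, the median over 11 genes was -0.51. That median is the value of LTB, whose signal of 68.9 with SR-IκBα lay below the floor, so it rests on a bound.

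Genes of the NF-κB pathway and its feedback regulators had a median of -0.44 over 21 measured members, 16 of them lower, again below all random lists (percentile 0, middle 95% from -0.22 to 0.22). TNFAIP3, which encodes the NF-κB inhibitor A20, was 2.71-fold lower on its brightest probe set but 1.09-fold higher on its other. NFKB2, a subunit precursor of the noncanonical pathway, was 2.16-fold lower on its brightest probe set, while 1 of its 3 probe sets was higher. TNFAIP2 was 2.05-fold lower and CYLD, a deubiquitinase acting on the pathway, at least 2.04-fold lower on its brightest probe set, with 3 probe sets above the floor that differed in direction. NFKBIE was 1.89-fold lower and RELB 1.83-fold lower. The subunit genes RELA and NFKB1 were 1.17-fold and 1.07-fold lower. MAP3K14, the kinase NIK of the noncanonical pathway, was 2.28-fold higher and was the 1 member at least 2-fold higher.

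Survival genes linked to NF-κB had a median of -0.43 over 10 measured members (7 lower, percentile 0.17). The early-response gene IER3 was among the brightest on the array, with a signal of 26729 in the vector control and 12577 with SR-IκBα, 2.13-fold lower. TNFAIP3, with the disagreement between its probe sets given above, is also on this list. MCL1, an antiapoptotic BCL2 relative, was 1.39-fold lower on its brightest of 5 probe sets, 2 of which were higher, and its ratio turned to 0.13 on the log2 scale without probe sets that can match several transcripts. The kinase gene PIM1 was 1.38-fold lower. BCL2L1, another antiapoptotic gene, was 1.24-fold higher on 1 of its 3 probe sets and near equal on the others. Adhesion, protease and matrix genes had a median of -0.36 over 14 measured members, 13 of them lower (percentile 0.09). The pentraxin gene PTX3 was 2.11-fold lower and was the 1 member past 2-fold. The adhesion receptor gene ICAM1 was 1.57-fold and 1.55-fold lower on its probe sets, the hyaluronan receptor gene CD44 1.64-fold lower on its brightest of 6 probe sets, and the laminin chain gene LAMB3 1.48-fold lower. Of the other 5 CD44 probe sets, 4 were 1.77-fold, 1.42-fold, 1.07-fold and 1.03-fold lower and 1 was 1.11-fold higher, and without probe sets that can match several transcripts its log2 ratio was -0.10. Without probe sets that can match several transcripts, the survival list had a median of -0.36 over 7 genes (percentile 7.79) and the adhesion list -0.26 over 11 (percentile 2.74), so their medians stayed negative but neither list stood apart.

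Over the 4 NF-κB lists together, 47 of 58 measured genes were lower and 13 were at least 2-fold lower, 22.4%. Among the other 7692 measured genes 137 were at least 2-fold lower, 1.78%. Matched random lists of 58 genes held a median of 1 such gene and at most 7.

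**Figure D2:**
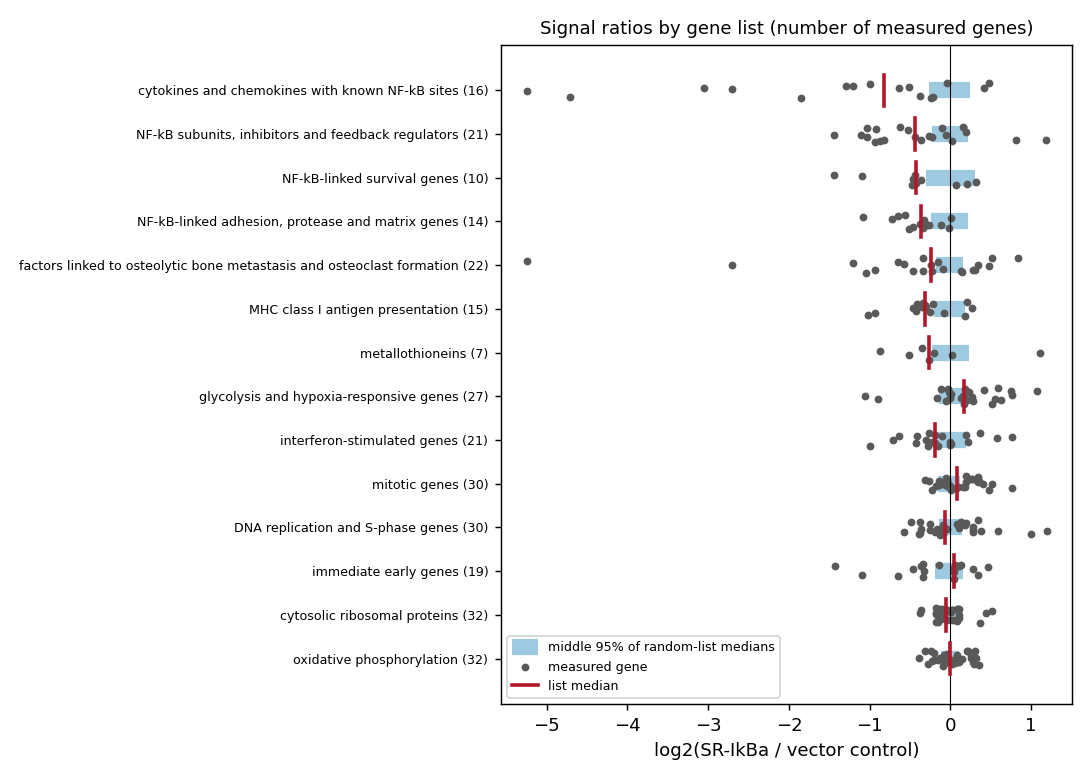
Dots are measured genes of each fixed list, placed by the log2 ratio of SR-IκBα to vector control (dots are spread vertically for visibility); red bars are list medians and blue bars the middle 95% of medians of 10000 signal-matched random lists. The medians of the 4 NF-κB lists, from -0.82 to -0.36, lie left of their blue bars, whereas those of the ribosomal protein list (-0.05) and the oxidative phosphorylation list lie inside.

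Factors linked to osteolytic bone metastasis and osteoclast formation were lower in 14 of 22 measured members, with a median of -0.23 (percentile 0.33). CXCL8, IL6 and CSF1, given above, and IL11, a cytokine that stimulates osteoclast formation, were the 4 members at least 2-fold lower. IL11 had a signal of 2979 in the vector control and 1445 with SR-IκBα, 2.06-fold lower, and 1.31-fold lower on its other probe set. HMOX1 was at least 1.91-fold lower and the chemokine receptor gene CXCR4 1.37-fold lower. The Notch ligand gene JAG1 was 1.79-fold higher, although its 3 probe sets differed in direction, and CCN2, the connective tissue growth factor gene, 1.40-fold higher. Without the 3 measured genes shared with the NF-κB lists the median was -0.15 over 19 genes, percentile 6.07, and the list no longer stood apart.

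Of the other 25 lists, 23 had enough measured members for a percentile, and 3 of these stood apart. MHC class I antigen presentation genes were lower, with 12 of 15 measured members lower, a median of -0.31 and a percentile of 0.05. TAPBP, which encodes the peptide-loading factor tapasin, was 2.02-fold lower, and the immunoproteasome subunit genes PSMB8 and PSMB10 were 1.91-fold and 1.38-fold lower. B2M, the common light chain, was 1.34-fold lower, from 20966 to 15591, while TAP1 and PSMB9 were 1.13-fold and 1.15-fold higher. The HLA genes resemble each other closely and their probe sets can share signal. With them left out, the median was -0.33 over 10 genes. Metallothioneins had a median of -0.27 over 7 measured members (percentile 0.97), with MT3 1.82-fold, MT1G 1.43-fold and MT1F 1.28-fold lower and MT1H 2.16-fold higher, but their near-identical sequences make single members uncertain. Random lists without matching on signal put this list at a percentile of 7.83, and no floor with a pseudocount of 1 at 4.92, so it did not stand apart there.

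Glycolysis and hypoxia-responsive genes were higher in 19 of 27 measured members, with a median of 0.17 (percentile 98.9). SLC2A3, a glucose transporter gene, was at least 2.12-fold higher, PFKFB3, a regulator of glycolysis, 1.69-fold and the hexokinase gene HK2 1.68-fold higher, and PGK1 was 1.54-fold higher. The pyruvate dehydrogenase kinase gene PDK1 was 2.07-fold lower. Random lists without matching on signal gave the same median a percentile of 97.3. Leaving out probe sets that can match several transcripts gave a median of 0.17 over 13 genes and a percentile of 90.6. In neither setting did the list stand apart, although its median was about as high.

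The other 20 lists with a percentile did not stand apart. Mitotic genes had a median of 0.09, DNA replication genes -0.07 and G1 cyclins with CDK inhibitors -0.05. Interferon-stimulated genes had a median of -0.19 (percentile 3.86) and endoplasmic reticulum chaperones 0.17 (percentile 95.2). Both stood apart under other settings, the interferon-stimulated genes with the median over probe sets (percentile 2.33) and the chaperones under 4 alternatives, with a median of 0.41 over 9 genes (percentile 99.8) without probe sets that can match several transcripts. Immediate early genes had a median of 0.04, although JUNB was at least 2.69-fold lower. Heat shock genes had 0.04, p53 targets 0.19, antioxidant genes -0.0019, amino acid stress genes -0.09, cholesterol synthesis genes -0.03 and fatty acid synthesis genes 0.03. TGF-beta response genes had 0.09, mesenchymal genes 0.09, epithelial genes -0.02, ribosomal proteins -0.05, oxidative phosphorylation genes -0.0039 and reference genes 0.09. Of 12 measured reference genes 7 were higher and 5 lower, and 1 was past 2-fold, TBP, 2.02-fold lower, from 686.4 to 340.6. The mean and the median differed in sign for DNA replication (mean 0.04), G1 cyclins (0.10), fatty acid synthesis (-0.03), amino acid stress (0.0025), immediate early (-0.19), oxidative phosphorylation (0.02), antioxidant (0.05) and reference genes (-0.09). Some medians changed sign with the setting. The median of the reference genes was -0.03 after quantile normalization, and those of the oxidative phosphorylation and antioxidant genes were above 0 after centring on the median. Without probe sets that can match several transcripts, p53 targets had -0.05 and DNA replication genes 0.08. With the median over probe sets, DNA replication genes had 0.04, oxidative phosphorylation genes 0.02 and leukocyte markers 0.02. With the floor at the 75th percentile, fatty acid synthesis genes had -0.13, immediate early genes -0.05 and antioxidant genes 0.08, and with the floor at the 25th, immediate early genes had -0.01. Luminal breast markers had a median of 0.12 over 10 measured members and leukocyte markers -0.03 over 6, of which ITGAM, an integrin subunit of myeloid cells, was at least 2.67-fold lower. Of the fibroblast markers 4 of 10 on the array were measured, with a median of -0.19, and DCN, the proteoglycan decorin, was lower on its brightest probe set, from 426.8 to below the floor, with a log2 ratio of -1.32 at the floor. Of the endothelial markers 1 of 7 was measured, PECAM1, at least 1.77-fold lower. With 28 percentiles computed, and 8 of 100 unchanged simulated lists standing apart, some isolated lists outside the limits arise by chance.

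Of the genes at least 2-fold lower, 36 had a further probe set above the floor, and the next-brightest was also lower in 22 of them, 61.1% (exact Clopper-Pearson 95% interval 43.5% to 76.9%), and at least 2-fold lower in 4. Of the genes at least 2-fold higher, 33 had one, and it was also higher in 16, 48.5% (30.8% to 66.5%), and at least 2-fold higher in 1. Over all 2246 genes with a further probe set above the floor, the next-brightest was past 2-fold in either direction in 81, 3.6%. The 2-fold genes were mostly of low signal. With the measured genes in 4 equal groups by signal, the second dimmest, with a median signal of 333.2, held 110 of the lower and 96 of the higher genes, while the brightest held 9 and 9. All 11 control probe sets for ribosomal RNA above the floor were lower on the SR-IκBα array, with a median log2 ratio of -0.53, and 1 further such probe set lay below the floor on both arrays. The ratio of the 5′ to the 3′ control probe set was 0.917 and 1.16 for GAPDH, and 0.769 and 0.742 for ACTB, in the vector control and SR-IκBα respectively.

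**Figure D3:**
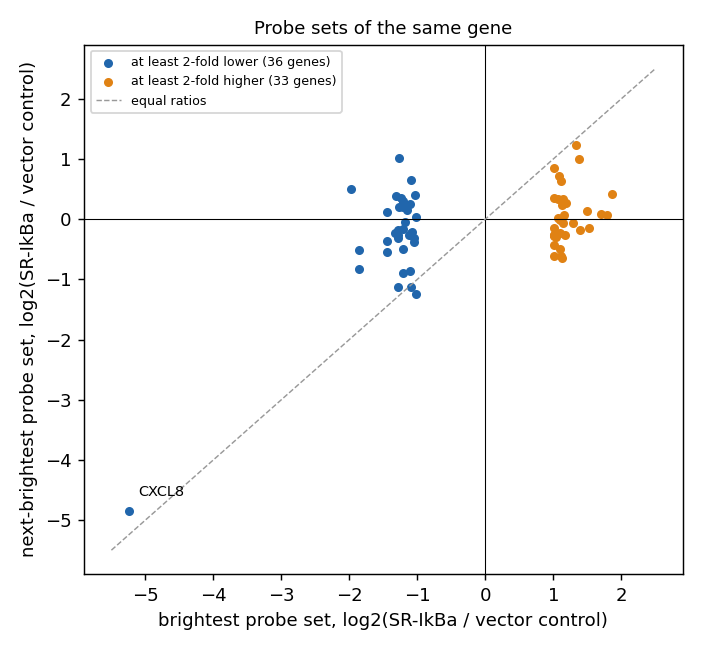
Each point is a gene at least 2-fold lower (blue, 36 genes) or higher (orange, 33 genes) on its brightest probe set (horizontal axis, log2 ratio of SR-IκBα to vector control), set against the ratio of its next-brightest probe set (vertical axis). CXCL8 lies near the line of equal ratios at -5.25 and -4.84, while most other genes lie nearer to 0 on the vertical axis.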

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

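The tests of an intensity-dependent difference and of the 2-fold lower genes of the NF-κB lists against random lists, and the test of the other 2-fold lower genes, were chosen after the results were seen. Probe sets without a single gene name entered no comparison. Among those above the floor, 7 of 590 with several gene symbols and 17 of 830 that the annotation does not list were at least 2-fold above the vector control array. They are listed here as signal outside the main measurement. In the opposite direction, 11 and 20 were at least 2-fold lower, and the median log2 ratios of these classes were 0.01 and -0.01. No gene is named for them.

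The first pattern is the lower level of the 4 NF-κB lists. An intensity-dependent difference between the arrays would lower random lists of like signal as well, but the lowest of their 4 central medians was -0.012, against list medians of -0.82 to -0.36. Whether the lower level is a ratio specific to the brightest probe set stays open, since 13 of 22 next-brightest probe sets were lower, 59.1% (exact 95% interval 36.4% to 79.3%). With the median over probe sets the 4 lists had percentiles of at most 0.47, but this setting cannot move the 36 of 58 genes with 1 probe set above the floor, and it still includes the brightest probe set in the others. With 1 array per group, an effect of SR-IκBα on NF-κB targets, which the design names, cannot be told apart from any other difference between the 2 cultures.

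The second pattern is the genes past 2-fold. For the NF-κB lists, measurement noise of single probe sets does not account for the count, since 0% of 10000 matched random lists held as many as 13 lower genes. This concerns the count and not each gene. Where these genes had a further probe set above the floor, the next-brightest was lower in CXCL8, IL1B and NFKB2 but higher in TNFAIP3 and CYLD. For the other 137 lower genes, 19 of 31 next-brightest probe sets were also lower, 61.3% (42.2% to 78.2%), which leaves noise open. For the 135 higher genes the share was 48.5%, which is what measurement noise of single probe sets predicts, so many of these higher genes may be noise. A biological difference in some of them was not excluded.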

How the results depend on the processing

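The alternatives that leave out genes on another primary list, CXC chemokine genes or HLA genes, or require both arrays above the floor, and the 4-fold counts with other floors, were chosen after the data were seen. The 5 primary lists had a negative median under every alternative run, from -1.11 to -0.51 for cytokines, -0.48 to -0.24 for pathway genes, -0.45 to -0.36 for survival genes, -0.38 to -0.26 for adhesion genes and -0.44 to -0.15 for bone metastasis factors. Of 56 alternative values, 53 stood apart as in the main setting. These include centring on the median, which shifts every gene alike and so cannot change a percentile. The exceptions were the survival list (-0.36, 7 genes) and the adhesion list (-0.26, 11 genes) without _x_at and _s_at probe sets. A further exception was the bone metastasis list (-0.15, 19 genes) without genes on another primary list. That setting removed CXCL8, IL6 and CSF1, each at least 2-fold lower. Without _x_at and _s_at probe sets the bone metastasis list kept 12 genes and stood apart (-0.44, percentile 0.07). The counts of 2-fold genes depended on the floor. Higher and lower genes numbered 710 and 877 with the floor at the 25th percentile, 16 and 21 at the 75th, 1172 and 1463 with no floor and a pseudocount of 1, 87 and 82 without _x_at and _s_at probe sets, 650 and 697 at 1.5-fold, 8 and 18 at 3-fold, and 82 and 83 when both arrays had to be above the floor. At 4-fold, higher and lower genes numbered 88 and 105 with the floor at the 25th percentile, 0 and 2 at the 75th, and 416 and 563 with no floor. With the other scalings and the median over probe sets both counts stayed within 1.5 times the main ones. No further scaling changed almost nothing, because the deposited arrays already shared a trimmed mean, and loess normalization changed little, so neither says much about stability. The same holds for centring, which moved every gene by the same small amount. The median over probe sets cannot move a gene with 1 probe set above the floor. Such values are part of the tally for named genes that follows. Of 363 alternative values for named genes, 321 lay within 0.43 log2 units of the main value and 42 moved further, mostly with another floor, and 0 genes past 2-fold changed sign, while MCL1, within 2-fold, did (0.13 without _x_at and _s_at probe sets). Among the context lists, endoplasmic reticulum chaperones stood apart under 4 alternatives (highest percentile 99.8), interferon-stimulated genes under 1 (percentile 2.33) and ribosomal proteins under 1 (percentile 2.44). No paired analysis was possible because each group has 1 array. Low signal limits dim genes, for which a fold below the floor is only a bound.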

Other observations

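The rule for bright genes below was set after the values were seen. Genes bright on both arrays gave further differences. Of 2724 genes with a signal over 681.6 (4 times the floor) on both arrays, 9 were at least 2-fold lower and 9 at least 2-fold higher, counting those whose probe sets above the floor all went the same way. Only IL11, MBNL1 and POLR3C had 2 such probe sets. The others had 1, so they met this condition by itself. Besides IER3, IL11 and TAPBP, the lower ones were EFHD2 (3.12-fold), DCTPP1 (2.20-fold), SPINT2, an inhibitor of serine proteases (2.19-fold), CSRP1 (2.13-fold), SDC4, the proteoglycan syndecan-4 (2.06-fold), and the splicing factor gene SF3B4 (1487 to 743). Besides SEM1 and MT1H, the higher ones were MAGEA6, a cancer-testis antigen with near-identical relatives (2.56-fold), CTNNAL1 (2.47-fold), PMPCB (2.28-fold), DPYSL2 (2.21-fold), POLR3C (2.09-fold, with a second probe set near equal), RSL24D1 (2.07-fold) and MBNL1 (2.01-fold). On its second probe set MBNL1 had a log2 ratio of 0.35.

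Among the fixed lists, ZEB1, a transcription factor that represses epithelial genes, was 2.13-fold higher, from 389.7 to 828.2, and its 2 probe sets above the floor were both higher. SNAI2, another such factor, was higher, from below the floor to 341.6, and CD24, a surface glycoprotein, at least 2.44-fold lower. Other members went the opposite way, with the epithelial genes EPCAM at least 1.87-fold and CLDN7 1.49-fold higher and the mesenchymal-list gene CD44 1.64-fold lower on its brightest probe set. The CD44 probe sets disagreed, as given above. The mesenchymal and epithelial lists as a whole did not stand apart, and these genes were chosen after their values were seen.

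Agreement between probe sets of a gene was compared with chance in each direction. Of 2246 genes with several probe sets above the floor, 17 had all of them at least 1.5-fold lower and 22 all at least 1.5-fold higher. Chance coincidence of independent probe-set noise was tested with 1000 shuffles of log2 ratios among probe sets of like signal. Such shuffles gave a median of 10 lower genes, and 2.4% gave as many as observed. They gave a median of 19 higher genes, and 28.2% gave as many. The count of lower genes was thus reached by few shuffles and that of higher genes by many, but the directions were not compared with each other. Probe sets of a gene measured the same RNA on each array, so their agreement does not show that a ratio would recur in other cultures. Probe sets that overlap in sequence also share noise that shuffling removes. The 17 lower genes included CXCL8, IL1B and ICAM1, the only ones on the NF-κB lists. The others, among them MAFF, CD24 and PIK3CD, are on none of those lists. The genes named here were picked after their values were seen.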
